A study of Oryza sativa with 18 samples.

How the data were processed

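The series holds 18 samples of rice leaf sheath from plants at the four-leaf stage, each hybridised as biotin-labelled cRNA to 1 Affymetrix 1-colour array. They fall into 6 groups of 3 biological replicates: the variety 9311 and the line NIL-BPH9, each at 0, 3 and 6 h of infestation with the brown planthopper (BPH), an insect that feeds on phloem sap. Per the labels, 9311 is susceptible and NIL-BPH9 resistant. All 0 h samples were taken without infestation, and uninfested plants at 3 h or 6 h were not analysed here, so time of day and infestation change together in each response.

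The deposited table gives 1 log2 value per probe set and array. Per the submitters' processing notes the values came from MAS5. Its version and settings are not given in the sources used here. The log2 scale and the scaling were read from the deposited values: the 2% trimmed mean of the linear signal lay between 500.076 and 500.088 on every array, the lowest log2 value was 0, and 24806 values were at 0. No detection calls were used here. The number of arrays limits the precision, and a signal near the array median (5.18 to 5.52 on the log2 scale over rice probe sets) may hold mostly background.

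Of 57381 probe sets, 187 were controls (123 with the prefix AFFX and 64 with the prefix RPTR) and were left out of the tests. Names came from the platform annotation through gene identifiers matched to the RefSeq gene table of assembly GCF_034140825.1 ASM3414082v1, which was used only for names and for which genes neighbour each other. Of 57194 rice probe sets, 22436 had exactly 1 gene, 95 had several and were not named, and 34663 were unnamed here. All 17905 genes matched the gene table, and 2453 of them had a name other than a LOC number.

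A probe set was tested when it lay at or above its array's median on at least 3 arrays, which left 33094. The main test was limma (version 3.58.1, in R 4.3.3): a fit of the 6 group means over all 18 arrays, contrasts for each comparison, eBayes with an intensity trend, and Benjamini-Hochberg adjustment with a threshold of 0.05. All adjusted p-values of genes are from limma. The difference between the lines over all times was fitted with time and line as terms. For statements on genes, the brightest tested probe set of each of 16053 genes was used, with probe sets of the suffix _x_at taken only where a gene had no other. The spread of a log2 change is its standard error (SE) from the fit.

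Of 31 gene lists fixed before the data were examined, 27 had a matched gene and 21 had the minimum of 5 measured genes. Lists were matched through gene symbols and synonyms, so members without a symbol are missing. The 21 lists were tested in 9 comparisons (189 tests, adjusted together) with limma's camera at a preset correlation of 0.01, and again with the correlation estimated. Of the 189 tests, 64 passed, and 28 of them also passed with an estimated correlation. In the 64 tests that passed, 0 medians and 0 means differed in sign from the test, and over all 189 tests the median or mean differed in 25. Untested for lack of members were ethylene biosynthesis and phloem proteins (2 measured genes each), class III peroxidases (2), seed storage proteins (3), volatile terpene synthases (1), pollen genes (0), and beta-1,3-glucanases, callose synthases, wall-associated kinases and NLR disease resistance proteins (0 matched each).

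The rule for named genes was also fixed before the data were examined: per comparison, the 6 largest rises and the 6 largest falls among called, named genes whose groups did not overlap, and the 2 largest rises and falls of each list that was called or had at least 3 called members. The genes printed are a selection of these. Windows of 1 Mb with at least 10 tested genes were compared with the rest of the genome by Fisher's exact test, as were chromosomes. Correlations between responses are across genes, which are not independent replicates. Where the comparisons share control arrays, 20 simulations of unchanged groups gave the value expected without any effect.

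The fit was tested on simulated data built from the real probe sets' means and spread, with 200 of 33094 probe sets changed in each of the 10 comparisons. Of 100 changes of 4-fold it recovered between 70 and 88, and of 100 changes of 2-fold between 43 and 75. A bar of 80 recovered 4-fold changes, set before this test was run, was missed in 5 of the 10 comparisons, and the fit was kept on the signs (all right), the median errors and the false calls. The missed probe sets had a median SD of 0.889 and the recovered ones 0.150, so a change in a noisy probe set can go uncalled. False calls were 5.19% of all calls, and the largest median error of a log2 change was 0.0349. The simulated noise was drawn independently for each probe set. Fewer probe sets were changed than the 2325 to 6188 called in the real comparisons, so these rates need not hold there.

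Alternatives were quantile normalization, centring each array on its median, no filter, a filter at the 60th percentile, a floor at the 25th percentile of all values, eBayes without the trend, only the groups of a comparison in the fit, the replicate number as a block, stricter thresholds, other windows, other handling of probe sets and lists, and leaving out each array in turn. These were chosen before the data were examined, except leaving out arrays for chromosomes and windows, which was added later with the 3 h and 6 h arrays alone and the split of shared arrays. Tables and figures used Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.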

Results

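Transcript levels were measured in leaf sheath of the planthopper-susceptible variety 9311 and of NIL-BPH9, a near-isogenic line that carries the resistance gene BPH9, before infestation (0 h) and after 3 h and 6 h of infestation, with 3 arrays in each of the 6 groups. Replicate arrays correlated at 0.956 to 0.967 and arrays of different groups at 0.940 to 0.960, across probe sets. The first principal component held 15.4% of the variance and separated the lines. On the fourth component (6.88%), replicate 3 of 9311 at 0 h stood at 74.5, apart from the other arrays (-46.9 to 31.6). Without that array 5118 probe sets passed in 9311 at 3 h and 3416 at 6 h, against 4906 and 2521 with it. The 3' to 5' signal ratios of 5 control pairs, a sign of RNA integrity, did not pass an exact permutation test between the lines (p = 0.497 for their mean, n = 9 arrays per line, two-sided). Within times the exact permutation p of that mean was 0.2 at 0 h, 0.1 at 3 h, where 9311 was higher, and 0.2 at 6 h, and 3 arrays against 3 cannot go below 0.1. Every response below is against the 0 h arrays of the same line, and time of day changed along with infestation.

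In 9311 after 3 h, transcripts of jasmonate signalling rose and transcripts of cell division fell. Of 12 measured JAZ genes, which encode repressors induced by jasmonate, 8 rose and 0 fell (10 rose when adjusted over the list alone), with a camera adjusted p of 1.85e-08. TIFY10C rose 2.56-fold (log2 1.36 ± 0.10 SE, n = 3 arrays per group, limma adjusted p = 3.04e-08) and TIFY11D rose 2.22-fold (1.15 ± 0.08). Of 20 cell division genes, 17 fell and 0 rose (19 fell when adjusted over the list alone), with a median log2 change of -0.88 and a camera adjusted p of 1.71e-16. OsMCM4 and OsMCM2, subunits of the replicative helicase, fell 3.54-fold (-1.82 ± 0.13) and 3.36-fold (-1.75 ± 0.15). Of 21 growth-regulating factor, YABBY and KNOX genes, chosen after values of 4 of them were seen, 11 fell and 2 rose in 9311 after 3 h, and in NIL-BPH9 2 fell and 2 rose. The mean log2 3' to 5' ratio of the 5 control pairs in 9311 was 1.61 ± 0.04 (SD, n = 3 arrays) at 0 h and 1.76 ± 0.06 at 3 h, with an exact permutation p = 0.1, the smallest that 3 arrays against 3 allow. In NIL-BPH9 it was 1.69 ± 0.08 at 0 h and 1.68 ± 0.03 at 3 h (exact permutation p = 0.9), a mean over pairs that moved in opposite directions. There the second actin pair went from 3.50 ± 0.13 to 3.24 ± 0.10, glyceraldehyde-3-phosphate dehydrogenase from 2.07 ± 0.12 to 1.82 ± 0.11 and cyclophilin from 0.71 ± 0.11 to 1.12 ± 0.12 (exact permutation p = 0.1 each).

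Of 14 jasmonate biosynthesis genes, 4 rose (5 adjusted over the list alone), with a camera adjusted p of 0.00388 and an adjusted p = 0.0619 with an estimated correlation. Among them AOS1, an allene oxide synthase, rose by a log2 of 0.96 ± 0.07 and OPR13 by 0.53 ± 0.06. Of 25 cytosolic ribosomal protein genes, 14 fell and 1 rose (17 and 2 adjusted over the list alone), and that list's call (0.000409) was lost, with adjusted p = 0.431 with an estimated correlation. RPL5 fell by 0.44 ± 0.08 and RPS4 fell by 0.40 ± 0.08 on the log2 scale. Of 7 proteinase inhibitor genes, 3 rose (4 adjusted over the list alone), with a camera adjusted p of 0.0497 and an adjusted p = 0.289 with an estimated correlation.

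Other named genes of this comparison belonged to several groups. OsBURP16 rose 3.69-fold (log2 1.88 ± 0.10), RFS 2.84-fold and Pir7b 2.57-fold. EXPA2, an expansin, rose by 1.22 ± 0.07, the sugar transporter gene SWEET1B by 1.19 ± 0.31 and the calmodulin-like gene CML4 by 0.82 ± 0.11. Smaller rises were those of MPK13, by 0.68 ± 0.16, the MAP kinase gene MPK3 by 0.60 ± 0.09 and the chitinase gene Cht2 by 0.57 ± 0.09. The homeobox gene Oskn1 fell by 4.49 ± 0.85 and Chib3H-a fell by 3.31 ± 0.77, both to levels under the array median at 3 h. MAKIBA3 fell by 2.89 ± 0.21, the expansin gene EXPA29 fell by 2.43 ± 0.25 and the YABBY gene OsYAB3 fell by 2.30 ± 0.22. DREB1B fell by 1.34 ± 0.17, GH3.8 of the auxin-conjugating family fell by 1.15 ± 0.23, and the chlorophyll-binding gene LHCP fell by 0.66 ± 0.09. The clock genes OsCCA1 and OsPRR95 fell by 0.82 ± 0.20 and fell by 0.58 ± 0.08. In all, 2518 probe sets rose and 2388 fell (4906 of 33094). Of the 527 that changed by at least 2-fold, 185 rose and 342 fell. The share that rose was 51.3%, and 48.9% and 49.2% without replicates 1 and 2 of 3 h. Of 16053 genes, 5582 had non-overlapping groups where chance gives 10%. With only these 6 arrays in the fit the count was 2486, and without replicate 2 of 0 h SWEET1B stood at 0.71 (adjusted p = 0.0678).

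In 9311 after 6 h, JAZ genes and WRKY factors rose, and cell division genes fell. Among the 12 JAZ genes 9 rose (10 adjusted over the list alone), with a median log2 change of 1.22 and a camera adjusted p of 3.94e-15. TIFY11B rose 3.24-fold (1.70 ± 0.06, limma adjusted p = 1.13e-12) and TIFY11A rose 2.99-fold (1.58 ± 0.20). Of 6 WRKY genes 3 rose (4 adjusted over the list alone, camera adjusted p = 0.000252), among them OsWRKY76 by 1.43 ± 0.11 and OsWRKY71 by 1.34 ± 0.18. Of the 20 cell division genes 12 fell (18 adjusted over the list alone, camera adjusted p = 1.97e-12), among them the histone gene H2B.10, which fell by 0.90 ± 0.10, and OsMCM5, which fell by 0.79 ± 0.13. The mean log2 3' to 5' ratio was 1.77 ± 0.09 (SD, n = 3 arrays), against 1.61 ± 0.04 at 0 h (exact permutation p = 0.1), and in NIL-BPH9 at 6 h 1.70 ± 0.03 (exact permutation p = 0.9).

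Several lists passed at the preset correlation only. Jasmonate biosynthesis had 3 of 14 genes that rose (7 adjusted over the list alone), with 0.00313 and an adjusted p = 0.0550 with an estimated correlation, and AOS1 rose by 0.58 ± 0.07 and the allene oxide cyclase gene OsAOC by 0.32 ± 0.07. Salicylate signalling had 2 of 7 that rose (3 adjusted over the list alone), NH3 by 0.58 ± 0.07 and OsNPR4 by 0.49 ± 0.14, with 0.0210 and an adjusted p = 0.0758 with an estimated correlation. AP2/ERF factors had 4 of 8 that rose and 1 that fell (4 and 1 adjusted over the list alone), with 0.0223 and an adjusted p = 0.108 with an estimated correlation. DREB1B rose by 1.49 ± 0.17 and DREB1E by 1.44 ± 0.14, DREB2B fell by 0.31 ± 0.09, and DREB1C stood at -0.31 ± 0.55 (adjusted p = 0.830). Proteinase inhibitors had 3 of 7 that rose (3 adjusted over the list alone), with 0.0180 and an adjusted p = 0.221 with an estimated correlation. Ribosomal proteins had 5 of 25 that fell and 1 that rose (9 and 2 adjusted over the list alone), with 0.00457 and an adjusted p = 0.520 with an estimated correlation.

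Pir7b rose 4.77-fold (2.25 ± 0.18), OSE727A of the proteinase inhibitor list by 1.57 ± 0.07, the chitinase gene Cht11 2.83-fold, LOX1.1 2.82-fold, the calmodulin-like gene CML31 by 0.94 ± 0.12, EXPA1 by 0.82 ± 0.16 and the sucrose transporter gene SWEET11 by 0.58 ± 0.07. OsCPS2 and CYP71Z7, genes of diterpene phytoalexin synthesis, fell by 1.26 ± 0.25 and fell by 1.17 ± 0.21, and OsCPS2 lay under the array median at 6 h. OsPMEI8 fell by 1.16 ± 0.14, the chromomethylase gene OsCMT3a fell by 0.91 ± 0.16 and the ribosomal gene RPL39C fell by 0.40 ± 0.05. In all, 1419 probe sets rose and 1102 fell (2521), 248 by at least 2-fold, and 4156 genes had non-overlapping groups where chance gives 10%. With only these 6 arrays in the fit the count was 805. Without replicate 2 of 0 h the adjusted p was 0.0643 for LOX1.1 (1.29), 0.0630 for OsAOC (0.26) and 0.150 for OsNPR4 (0.39). Without replicate 1 of 6 h it was 0.0541 for LOX1.1 and 0.125 for OsNPR4, and without replicates 2 and 3 of 6 h it was 0.0544 and 0.0529 for OsNPR4.

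In NIL-BPH9 after 3 h, the linalool synthase gene OsLIS rose 19.5-fold (log2 4.29 ± 0.23 SE, n = 3 arrays per group, limma adjusted p = 1.77e-10), and JAZ and jasmonate biosynthesis genes rose as groups. At 0 h OsLIS stood at 5.82 ± 0.36 (SD) in NIL-BPH9, near the array medians. Among the 12 JAZ genes 11 rose (11 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 2.18e-12. TIFY9 rose 10.1-fold (3.33 ± 0.68) from a 0 h level under the array median, TIFY11C 7.16-fold (2.84 ± 0.13) and TIFY10C 4.74-fold (2.25 ± 0.10). Of the 14 jasmonate biosynthesis genes 10 rose (11 adjusted over the list alone, camera adjusted p = 9.96e-09), among them AOS1 by 1.21 ± 0.07 and OPR1 by 2.29-fold. Of 13 phenylpropanoid genes 6 rose (7 adjusted over the list alone, camera adjusted p = 0.00859), among them OsCAD6, a cinnamyl alcohol dehydrogenase gene, by 2.58 ± 0.23 and Os4CL5 by 0.80 ± 0.15.

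Of 28 primary cell wall genes 12 rose and 2 fell (14 and 2 adjusted over the list alone), with 1.30e-05 and an adjusted p = 0.146 with an estimated correlation, and the expansin genes EXPA2 and EXPB2 rose by 2.30 ± 0.07 and 1.90 ± 0.31. Of the 6 WRKY genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), with 0.0411 and an adjusted p = 0.108 with an estimated correlation, and OsWRKY76 and OsWRKY62 rose by 1.97 ± 0.11 and 1.41 ± 0.22. Of 9 diterpene phytoalexin genes 3 rose (4 adjusted over the list alone), with 0.0175 and an adjusted p = 0.0659 with an estimated correlation, among them CYP99A3 by 1.14 ± 0.22 and CYP99A2 by 0.98 ± 0.20. Of 10 pathogenesis-related genes 3 rose (4 adjusted over the list alone), with 0.0235 and an adjusted p = 0.0764 with an estimated correlation, and Cht11 rose by 1.03 ± 0.12. Of 8 AP2/ERF genes 4 fell and 1 rose (4 and 1 adjusted over the list alone), with 0.0300 and an adjusted p = 0.120 with an estimated correlation: DREB1B fell by 2.21 ± 0.17 and DREB1A fell by 1.23 ± 0.16. Of 7 clock genes 4 fell and 1 rose (6 and 1 adjusted over the list alone), with 0.0199 and an adjusted p = 0.218 with an estimated correlation: OsPRR95 fell by 1.06 ± 0.08 and OsCCA1 fell by 0.85 ± 0.20.

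GH3.8 rose 2.01-fold. Oskn1 fell by 4.69 ± 0.85, to a level under the array median, the germin-like gene OsGER2 fell by 1.71 ± 0.07, the copper transporter gene OsCOPT1 fell by 1.43 ± 0.10 and CML15 fell by 1.25 ± 0.18. IAA9 fell by 0.86 ± 0.22 and the sucrose synthase gene OsSUS4 fell by 0.62 ± 0.05. Of the 20 cell division genes 4 fell and 1 rose, and that list did not pass the camera test. In all, 2520 probe sets rose and 2140 fell (4660), 637 by at least 2-fold, and 6744 genes had non-overlapping groups where chance gives 10%. For IAA9 the adjusted p was 0.0643 without replicate 3 of 0 h (-0.73), and 0.0528 and 0.0575 without replicates 1 and 2 of 3 h (-0.77 and -0.74).

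In NIL-BPH9 after 6 h, OsLIS stood 14.3-fold above 0 h (3.83 ± 0.23, limma adjusted p = 8.18e-10), and JAZ, WRKY and AP2/ERF genes rose. Among the 12 JAZ genes 10 rose (10 adjusted over the list alone), with a median log2 change of 1.61 and a camera adjusted p of 1.21e-12. TIFY11A rose 8.14-fold (3.03 ± 0.20), TIFY9 7.90-fold (2.98 ± 0.68) from a 0 h level under the array median, TIFY11C 5.98-fold (2.58 ± 0.13) and TIFY11E 5.92-fold (2.57 ± 0.11). Of the 6 WRKY genes 4 rose (4 adjusted over the list alone, camera adjusted p = 0.00145), OsWRKY76 by 2.44 ± 0.11 and OsWRKY71 by 2.35 ± 0.18. Of the 8 AP2/ERF genes 4 rose (4 adjusted over the list alone, camera adjusted p = 0.00145), DREB1G by 2.40 ± 0.24 and DREB1E by 1.82 ± 0.14.

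Of the 14 jasmonate biosynthesis genes 6 rose (10 adjusted over the list alone, camera adjusted p = 7.36e-05), AOS2 by 1.07 ± 0.20 and AOS1 by 0.86 ± 0.07. Of the 7 salicylate genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00556): NH3 rose by 0.73 ± 0.07, and the isochorismate synthase gene OsICS fell by 0.59 ± 0.17. Of the 10 pathogenesis-related genes 4 rose (5 adjusted over the list alone, camera adjusted p = 0.00799), and Cht11 rose by 1.91 ± 0.12. Of the 25 ribosomal protein genes 3 rose and 1 fell (8 and 1 adjusted over the list alone), with 0.0223 and an adjusted p = 0.601 with an estimated correlation, and RPS27AA rose by 0.37 ± 0.07. CML31 rose by 1.63 ± 0.12, OsCAD6 by 1.90 ± 0.23, EXPB2 by 1.65 ± 0.31 and MPK3 by 0.78 ± 0.09.

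Oskn1 and APO2 fell by 3.28 ± 0.85 and fell by 2.22 ± 0.56, and the flowering gene OsHd1 fell by 1.45 ± 0.27, all to levels under the array median at 6 h. OsGER6 fell by 1.26 ± 0.12, Os4CL1 fell by 1.24 ± 0.19, the clock gene OsPRR73 fell by 0.68 ± 0.20 and OsSUS6 fell by 0.59 ± 0.10. In all, 2739 probe sets rose and 3449 fell (6188), 923 by at least 2-fold, and 7281 genes had non-overlapping groups where chance gives 10%. The share that rose was 44.3%, and 65.3% with each array centred on its median, so the balance of small rises and falls depends on the scaling. Without replicate 3 of 0 h the count was 3533 and the share that rose 52.9%, and without replicate 2 of 6 h the count was 4063. Without that array of 6 h the adjusted p was 0.0543 for Oskn1 (-2.84), 0.0510 for APO2 (-1.83) and 0.0527 for OsICS. Without replicate 3 of 0 h it was 0.102 for OsICS and 0.138 for OsPRR73. Without replicate 1 of 6 h it was 0.0864 for OsPRR73, and without replicate 3 of 6 h it was 0.0655 for OsICS and 0.0665 for OsPRR73.

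**Figure D1:**
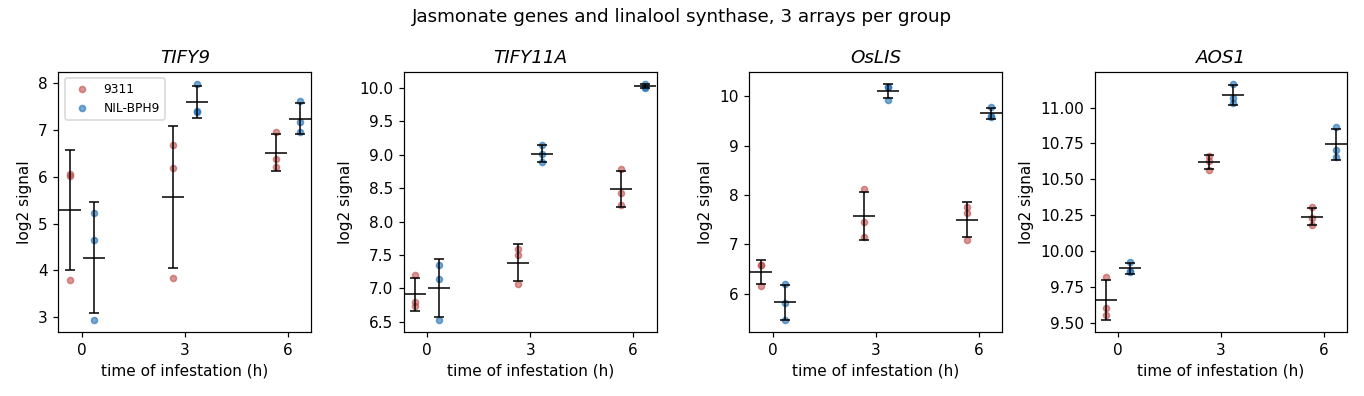
Log2 signal (y axis) of 3 JAZ or jasmonate synthesis genes and of OsLIS at 0, 3 and 6 h of infestation (x axis), with a point per array, a bar at the mean of 3 arrays and whiskers of 1 SD. OsLIS rose by 4.29 in NIL-BPH9 after 3 h, and for OsLIS, TIFY11A and AOS1 every NIL-BPH9 array lay above every 9311 array at 3 h and at 6 h, while for TIFY9 the lines overlapped at 6 h.

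Before infestation the lines already differed in OsNAS1, OsNAAT1, cell division and JAZ genes. In NIL-BPH9 the nicotianamine synthase gene OsNAS1 was 5.75-fold higher (log2 2.52 ± 0.07 SE, n = 3 arrays per group, limma adjusted p = 8.54e-15) and OsNAAT1, a nicotianamine aminotransferase gene, 2.75-fold higher (1.46 ± 0.06). Of the 20 cell division genes 16 were lower in NIL-BPH9 and 0 higher (17 lower adjusted over the list alone), with a median of -0.85 and a camera adjusted p of 2.18e-12. OsMCM2 and OsMCM5 were lower, at -1.13 ± 0.15 and -1.13 ± 0.13. Of the 21 growth-regulating factor, YABBY and KNOX genes 8 were lower and 2 higher. At 0 h the log2 3' to 5' ratio was higher in NIL-BPH9 for actin (2.79 ± 0.04 against 2.69 ± 0.01, SD), the second actin pair (3.50 ± 0.13 against 3.11 ± 0.13) and glyceraldehyde-3-phosphate dehydrogenase (2.07 ± 0.12 against 1.84 ± 0.05), and lower for cyclophilin (0.71 ± 0.11 against 0.90 ± 0.10), with an exact permutation p = 0.1 each, which is the smallest possible. Of the 12 JAZ genes 6 were higher and 0 lower (6 adjusted over the list alone, camera adjusted p = 0.00378), among them TIFY11B at 0.68 ± 0.06. Of the 7 clock genes 3 differed at 0 h, with OsPRR95 higher by 0.41 ± 0.08, OsPRR1 by 0.31 ± 0.09 and GI by 0.17 ± 0.05 in NIL-BPH9.

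Of the 25 ribosomal protein genes 17 were lower in NIL-BPH9 (17 adjusted over the list alone), with 1.19e-06 and an adjusted p = 0.282 with an estimated correlation, among them RPS27AA at -0.45 ± 0.07 and RPS10-1 at -0.41 ± 0.06. Of the 28 primary wall genes 13 were lower and 2 higher (14 and 2 adjusted over the list alone), with 0.000438 and an adjusted p = 0.221 with an estimated correlation, among them EXPA29 at -1.54 ± 0.25 and EXPA2 at -0.97 ± 0.07. Of 34 auxin response genes 9 were higher and 1 lower (11 and 3 adjusted over the list alone), with 0.00536 and an adjusted p = 0.102 with an estimated correlation: GH3.2 was higher by 1.30 ± 0.09, and GH3.8 stood at -0.87 ± 0.23. Of the 6 WRKY genes 2 were higher (3 adjusted over the list alone), with 0.0175 and an adjusted p = 0.0687 with an estimated correlation, OsWRKY76 by 0.86 ± 0.11 and OsWRKY62 by 0.83 ± 0.22. Of the 7 proteinase inhibitor genes 3 were higher (3 adjusted over the list alone), with 0.0240 and an adjusted p = 0.240 with an estimated correlation, and OSE727A was higher by 0.80 ± 0.07.

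TRS130 was 4.50-fold higher in NIL-BPH9 (2.17 ± 0.12), the germin-like genes GLP2 and OsGER6 4.37-fold and 2.59-fold higher, and ML 2.67-fold higher. The pathogenesis-related genes Cht2 and PBZ1 were higher by 0.81 ± 0.09 and 0.64 ± 0.06, CYP71Z7 by 0.82 ± 0.21, CYP99A2 by 0.67 ± 0.20 and the heat stress factor gene HSFA2C by 0.76 ± 0.10. The growth-regulating factor gene OsGRF5 stood at -1.54 ± 0.20, GL2-3 at -1.44 ± 0.24 and the glutaredoxin gene GRXC3 at -1.37 ± 0.19. In all, 2290 probe sets were higher and 2479 lower in NIL-BPH9 (4769), and 5213 genes had non-overlapping groups where chance gives 10%. Of the 570 that differed by at least 2-fold, 319 were higher and 251 lower. The share higher was 48.0%, and 38.6% with each array centred on its median. Without replicates 1 and 3 of 9311 it was 52.3% and 50.7%. With only these 6 arrays in the fit the count was 1734. Without replicate 3 of NIL-BPH9 the adjusted p was 0.0801 for OsWRKY62 (0.67), 0.0713 for CYP71Z7 (0.67) and 0.0871 for CYP99A2, for which it was 0.125 without replicate 1 of 9311 (0.46) and 0.0844 without replicate 2 of NIL-BPH9. For GH3.8 it was 0.0659 without replicate 2 of 9311 (-0.77) and 0.0548 without replicate 1 of NIL-BPH9.

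**Figure D2:**
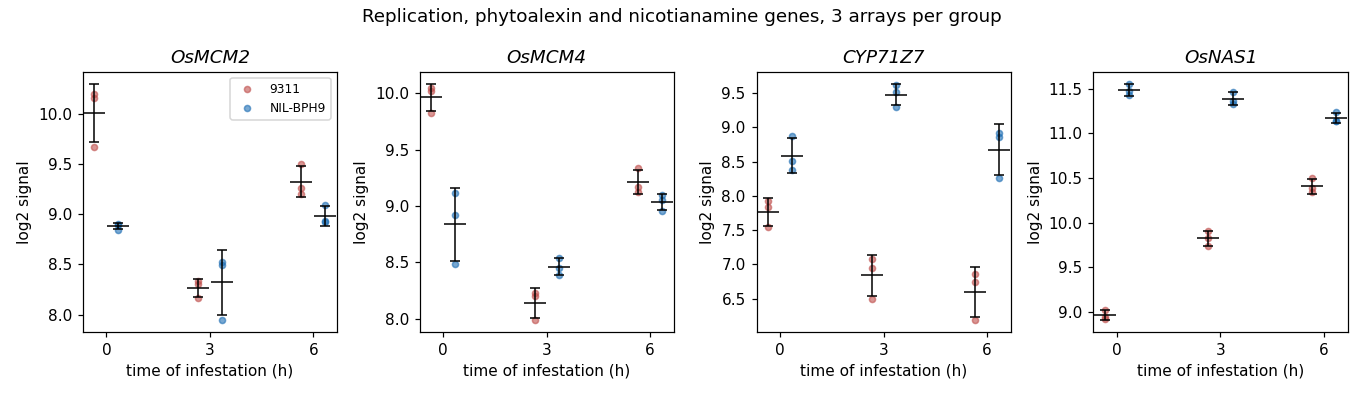
Log2 signal (y axis) of 2 replicative helicase genes, a phytoalexin gene and OsNAS1 at 0, 3 and 6 h (x axis), with a point per array, a bar at the mean of 3 arrays and whiskers of 1 SD. OsMCM2 and OsMCM4 were highest in 9311 at 0 h, and OsNAS1 was higher in NIL-BPH9 by 2.52 at 0 h and by 0.76 at 6 h.

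At 3 h, diterpene phytoalexin, JAZ, WRKY, jasmonate biosynthesis and pathogenesis-related genes were higher in NIL-BPH9. Of the 9 phytoalexin genes 7 were higher and 0 lower (7 adjusted over the list alone), with a median log2 difference of 1.79 and a camera adjusted p of 1.52e-05. The momilactone gene KSL4 was higher by 3.94 ± 0.96 and the cytochrome P450 genes CYP76M8 and CYP71Z7 by 2.85 ± 0.65 and 2.64 ± 0.21 (limma adjusted p = 5.17e-08 for CYP71Z7, n = 3 arrays per group), where KSL4 and CYP76M8 lay under the array median in 9311. Of the 12 JAZ genes 7 were higher (8 adjusted over the list alone, camera adjusted p = 3.56e-09), TIFY11C by 1.91 ± 0.13 and TIFY11A by 1.63 ± 0.20. OsLIS was 5.80-fold higher (2.54 ± 0.23).

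Of the 6 WRKY genes 3 were higher (3 adjusted over the list alone, camera adjusted p = 0.000252), OsWRKY76 5.09-fold and OsWRKY62 4.34-fold. Of the 14 jasmonate biosynthesis genes 6 were higher (10 adjusted over the list alone, camera adjusted p = 9.03e-06), the lipoxygenase gene LOX9 by 1.09 ± 0.19 and OPR1 by 1.02 ± 0.24. Of the 10 pathogenesis-related genes 5 were higher (7 adjusted over the list alone, camera adjusted p = 2.83e-05), PBZ1 by 0.72 ± 0.06 and Cht11 by 0.67 ± 0.12. Of 6 photosynthesis genes 1 was higher (1 adjusted over the list alone), LHCP by 0.66 ± 0.09, with 0.0303 and an adjusted p = 0.236 with an estimated correlation.

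ML was higher by 2.57 ± 0.07, OsCAD6 by 1.47 ± 0.23, GH3.8 by 1.29 ± 0.23, GH3.2 by 1.28 ± 0.09, OSE727A by 1.16 ± 0.07 and Os4CL5 by 0.90 ± 0.15. The glutaredoxin genes GRXC1 and GRXC10 were lower in NIL-BPH9, at -1.69 ± 0.09 and -1.58 ± 0.06, as were the ethylene signalling gene OsEIL1 at -1.16 ± 0.10, OsGER2 at -0.90 ± 0.07, IAA18 at -0.80 ± 0.17, SAUR39 at -0.79 ± 0.09 and SWEET2A at -0.46 ± 0.06. None of the 7 clock genes passed the limma test between the lines at 3 h or 6 h (0 called, 1 at an unadjusted p under 0.05), and the largest difference at 3 h was 0.301. In all, 1407 probe sets were higher and 1061 lower (2468), 559 by at least 2-fold, and 5610 genes had non-overlapping groups where chance gives 10%. For KSL4 the adjusted p was 0.0575 and 0.0637 without replicates 1 and 3 of NIL-BPH9 (3.85 and 3.76). For CYP76M8 it was 0.0526 and 0.0579 without replicates 2 and 3 of 9311 (2.46 and 2.33).

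At 6 h, OsLIS, phytoalexin, JAZ, WRKY and pathogenesis-related genes were higher in NIL-BPH9. OsLIS was 4.47-fold higher (2.16 ± 0.23, limma adjusted p = 2.21e-06, n = 3 arrays per group). Of the 9 phytoalexin genes 4 were higher (6 adjusted over the list alone, camera adjusted p = 0.000133), CYP71Z7 by 2.08 ± 0.21 and OsCPS2, under the array median in 9311, 3.47-fold. Of the 12 JAZ genes 8 were higher (8 adjusted over the list alone, camera adjusted p = 4.10e-08), TIFY11E by 1.69 ± 0.11 and TIFY11A by 1.54 ± 0.20. Of the 6 WRKY genes 3 were higher (4 adjusted over the list alone, camera adjusted p = 0.000898), OsWRKY76 by 1.87 ± 0.11 and OsWRKY62 by 1.56 ± 0.22. Of the 10 pathogenesis-related genes 5 were higher (5 adjusted over the list alone, camera adjusted p = 0.000144), Cht6 by 0.93 ± 0.21 and PBZ1 by 0.79 ± 0.06.

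Of the 8 AP2/ERF genes 4 were higher (5 adjusted over the list alone), with 0.00382 and an adjusted p = 0.0509 with an estimated correlation, and DREB1A was higher by 1.06 ± 0.16. Of 40 heat shock genes 12 were higher and 1 lower (12 and 1 adjusted over the list alone), with 0.00201 and an adjusted p = 0.0659 with an estimated correlation, and HSFA4D was higher by 0.81 ± 0.18. Of the 7 salicylate genes 3 were higher (3 adjusted over the list alone), with 0.0195 and an adjusted p = 0.0716 with an estimated correlation, NH1 by 0.46 ± 0.10 and NH3 by 0.41 ± 0.07. Of the 14 jasmonate biosynthesis genes 3 were higher (3 adjusted over the list alone), with 0.0199 and an adjusted p = 0.113 with an estimated correlation, AOS2 by 0.95 ± 0.20. Of the 7 proteinase inhibitors 2 were higher (3 adjusted over the list alone), with 0.0105 and an adjusted p = 0.201 with an estimated correlation. Of the 28 primary wall genes 9 were lower and 3 higher (10 and 4 adjusted over the list alone), with 0.0399 and an adjusted p = 0.445 with an estimated correlation: EXPA1 stood at -1.11 ± 0.16 and EXPB2 was higher by 1.11 ± 0.31.

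GLP2 was higher by 2.09 ± 0.25, TRS130 by 1.97 ± 0.12 and CML31 by 1.45 ± 0.12. Oskn1 and APO2 were lower, at -3.30 ± 0.85 and -2.10 ± 0.56, and lay under the array median in NIL-BPH9. OsGER2 stood at -1.88 ± 0.07, the dehydrin gene RAB21 at -1.60 ± 0.19, Os4CL1 at -1.31 ± 0.19, SWEET15 at -1.14 ± 0.28 (under the array median in NIL-BPH9), the laccase gene LAC4 at -1.10 ± 0.10 and SWEET11 at -0.77 ± 0.07. In all, 1903 probe sets were higher and 1833 lower (3736), 555 by at least 2-fold, and 6301 genes had non-overlapping groups where chance gives 10%. The share higher was 50.9%, and 61.3% with each array centred on its median, or 49.1% with only these 6 arrays in the fit. Leaving out 1 array ended the call of EXPB2 (without replicate 1 of 9311 or 2 or 3 of NIL-BPH9, adjusted p = 0.152, 0.0971 and 0.0915), Oskn1 (1 of 9311 or 2 of NIL-BPH9, 0.0532 and 0.0696), APO2 (2 or 3 of either line, 0.0615 to 0.0888) and SWEET15 (2 of 9311 or 1 of NIL-BPH9, 0.0738 and 0.0712).

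The response at 3 h differed between the lines for OsLIS and cell division genes. OsLIS rose more in NIL-BPH9, by a log2 of 3.16 ± 0.32 (limma adjusted p = 3.13e-06, n = 3 arrays per group). Of the 20 cell division genes 15 had a higher response in NIL-BPH9 (17 higher and 1 lower adjusted over the list alone), with a median of 0.88 and a camera adjusted p of 1.41e-11, among them OsMCM4 at 1.44 ± 0.18 and H2B.10 at 1.42 ± 0.15. Of the 12 JAZ genes 6 had a higher and 1 a lower response (8 and 2 adjusted over the list alone), with 0.0115 and an adjusted p = 0.0521 with an estimated correlation, TIFY11C at 1.96 ± 0.18 and TIFY11A at 1.53 ± 0.28. Of the 14 jasmonate biosynthesis genes 3 had a higher response (4 adjusted over the list alone), with 0.00905 and an adjusted p = 0.0829 with an estimated correlation, and OPR1 stood 2.30-fold higher.

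Of the 25 ribosomal protein genes 12 had a higher response in NIL-BPH9 (16 higher and 1 lower adjusted over the list alone), with 0.000154 and an adjusted p = 0.396 with an estimated correlation, and RPS10-1 stood at 0.58 ± 0.09. Of the 9 phytoalexin genes 4 had a higher and 1 a lower response (6 and 2 adjusted over the list alone), with 0.0426 and an adjusted p = 0.108 with an estimated correlation: KSL4, under the array median in 9311, stood at 5.05 ± 1.36 and CYP71Z7 at 1.82 ± 0.30. Of the 28 primary wall genes 9 were higher and 2 lower (13 and 3 adjusted over the list alone), with 0.00368 and an adjusted p = 0.282 with an estimated correlation, and EXPA29 stood at 2.76 ± 0.36. Of the 34 auxin genes 8 had a lower and 1 a higher response (9 and 1 adjusted over the list alone), with 0.0109 and an adjusted p = 0.122 with an estimated correlation, IAA9 at -1.24 ± 0.30 and GH3.8 at 2.15 ± 0.33. Of 26 sugar transport and cleavage genes 5 had a lower response (7 adjusted over the list alone), with 0.0459 and an adjusted p = 0.0894 with an estimated correlation, and the invertase gene OsCIN4 stood at -1.03 ± 0.30.

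The aquaporin gene OsPIP2;5 had a higher response in NIL-BPH9, at 2.37 ± 0.30, and OsCAD6 at 1.96 ± 0.33. Lower responses were those of OsBURP16 at -1.72 ± 0.15, GRXC10 at -1.51 ± 0.09, OsYSL13 at -1.46 ± 0.19 and OsMFT1 at -1.24 ± 0.14. In all, 1920 probe sets had a higher and 1562 a lower response in NIL-BPH9 (3482), 603 by at least 2-fold. The share higher was 55.1%, and 49.2% of 4552 without replicate 1 of 9311 at 0 h. Across 16053 genes the responses of the lines at 3 h correlated with a Pearson r of 0.242 and a Spearman rho of 0.205, where the simulated r without any effect was -0.00162. The jackknife SE of r, over all arrays without regard to groups, was 0.0969. With no filter on dim probe sets the r was 0.152. Of 1176 genes called in both lines 962 had the same sign, with 707 up in both against 199 for independent lists and 255 down in both against 145. The responses share each gene's estimate of spread in the fit, so these lists are not fully independent. The calls of OPR1, OsCIN4 and KSL4 each ended without any 1 of 8, 7 and 4 of the 12 arrays (adjusted p = 0.0509 to 0.0806, 0.0557 to 0.0964 and 0.0528 to 0.0557), and that of OPR1 also with no filter (0.0689).

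The response at 6 h differed between the lines for OsLIS, cell division and JAZ genes. OsLIS rose more in NIL-BPH9 by 2.78 ± 0.32 (limma adjusted p = 3.97e-05, n = 3 arrays per group). Of the 20 cell division genes 11 had a higher response in NIL-BPH9 (15 adjusted over the list alone, median 0.55, camera adjusted p = 1.43e-09), H2B.10 at 1.12 ± 0.15 and OsMCM4 at 0.95 ± 0.18. Of the 12 JAZ genes 4 had a higher response (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00855), TIFY11A at 1.45 ± 0.28 and TIFY11C at 1.35 ± 0.18. Of the 25 ribosomal protein genes 9 had a higher response (14 higher and 1 lower adjusted over the list alone), with 5.55e-05 and an adjusted p = 0.357 with an estimated correlation, RPS27AA at 0.60 ± 0.10. Of the 9 phytoalexin genes 3 had a higher response (5 higher and 1 lower adjusted over the list alone), with 0.0413 and an adjusted p = 0.108 with an estimated correlation, CYP71Z7 at 1.26 ± 0.30. Of the 14 jasmonate biosynthesis genes 0 were called (0 adjusted over the list alone), and that list did not pass (camera adjusted p = 0.109), nor did the primary wall (0.257), auxin (0.0551) and sugar lists (0.266).

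OsGRF5 at 1.61 ± 0.29, EXPB2 at 1.52 ± 0.44, OsYAB3 at 1.51 ± 0.31 and OsCAD6 at 1.46 ± 0.33 had a higher response in NIL-BPH9. RAB21 had a lower response at -2.25 ± 0.27, as had OsNAS1 at -1.76 ± 0.09, OsHd1 (under the array median in NIL-BPH9 at 6 h) at -1.40 ± 0.38, OsGER2 and the sucrose phosphate synthase gene OsSPS4F at -1.06 ± 0.09 and -1.06 ± 0.14, and SWEET11 at -0.93 ± 0.10. In all, 1268 probe sets had a higher and 1057 a lower response (2325), 334 by at least 2-fold. Across genes the responses of the lines at 6 h correlated with a Pearson r of 0.295 and a Spearman rho of 0.218, where the simulated r was -0.00278. The jackknife SE of r over arrays was 0.151, so r lay under 2 SE from 0, and it was 0.191 without replicate 1 of 9311 at 0 h. With no filter the r was 0.166. In all 731 of 862 genes called in both had the same sign. The count of 2325 was 1424 without replicate 2 of 9311 at 6 h, 1477 without replicate 3 of NIL-BPH9 at 0 h, and 1527 and 1542 without replicates 2 and 3 of NIL-BPH9 at 6 h. It was 4052 without replicate 1 of 9311 at 0 h. It was 1309 without the intensity trend and 1221 with only the 12 arrays of the comparison. The share higher was 54.5%, or 68.4% with each array centred on its median and 44.7% without replicate 1 of 9311 at 0 h. The calls of EXPB2 and OsHd1 ended without any 1 of 7 and 6 of the 12 arrays (adjusted p = 0.0510 to 0.107 and 0.0534 to 0.0977) and with no filter (0.0641 and 0.0654), and that of EXPB2 with the replicate block (0.0523).

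**Figure D3:**
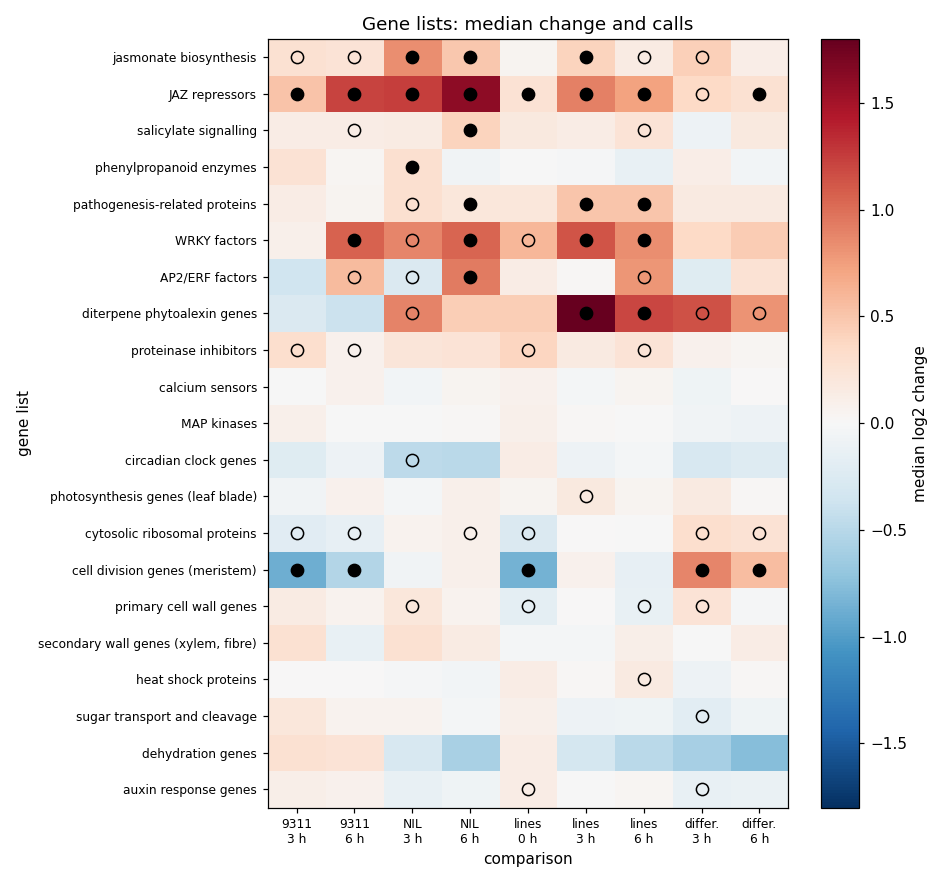
Median log2 change (colour) of 21 gene lists (y axis) in 9 comparisons (x axis: responses of 9311 and NIL-BPH9, differences between the lines, and differences between their responses). Circles mark the 64 list tests that passed, filled for the 28 that also passed with an estimated correlation.

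Over all times, TRS130, GLP2, CYP71Z7 and ML were higher in NIL-BPH9, by 1.99 ± 0.08 (limma adjusted p = 1.05e-13, n = 9 arrays per line), 1.96 ± 0.15, 1.84 ± 0.21 and 1.76 ± 0.13 on the log2 scale. OsWRKY76 was higher by 1.69 ± 0.15, TIFY11E by 1.25 ± 0.13, GH3.2 by 1.11 ± 0.08 and PBZ1 by 0.71 ± 0.04. OsGER2 was lower in NIL-BPH9 at -1.20 ± 0.11, the glutathione transferase gene GST-I at -0.88 ± 0.08, GRXC1 at -0.84 ± 0.14 and the potassium channel gene OsTPK2 at -0.82 ± 0.12. In all, 1956 probe sets were higher and 1605 lower (3561). The share higher was 54.9%, and 49.7% on the 3 h and 6 h arrays alone. Of the 473 that differed by at least 2-fold, 339 were higher and 134 lower. At each of 0, 3 and 6 h, which share no arrays, 251 genes were called higher in NIL-BPH9, where independent lists give 6.58, and 76 were called lower, where they give 5.97. The times share each gene's estimate of spread in the fit, so these lists are not fully independent.

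Genes that differed over all times were unevenly spread over the genome. On chromosome 8, 221 of 1064 tested genes were called (20.8%, Fisher's exact adjusted p = 1.48e-07), and on chromosome 12 17.5% (adjusted p = 0.0461), while chromosomes 5, 6 and 7 had fewer, at 12.4%, 11.3% and 11.4% (adjusted p = 0.0461, 0.00332 and 0.00350). On the 3 h and 6 h arrays alone the calls of chromosomes 5, 7 and 12 ended (adjusted p = 0.441, 0.0763 and 0.0763). With any 1 of the 18 arrays left out, chromosomes 8 and 6 passed 18 times, 7 17 times, and 5 and 12 10 times each, while chromosomes 1 and 2, which had not passed on all arrays (adjusted p = 0.0898 and 0.0702), passed 12 and 10 times. Counting only genes called at 0, 3 and 6 h alike, chromosomes 6 and 7 did not pass (0.0956 and 0.0999). In that setting chromosome 12 had the highest share, 5.26% (Fisher's exact adjusted p = 1.97e-07), ahead of chromosome 8 with 4.42% (2.73e-06). Chromosome 11 also passed with more called genes (0.031), and chromosomes 2 and 5 passed with fewer (2.4e-05 and 0.0138). Of 357 windows, 14 held more called genes than the rest of the genome, with 196 of 430 tested genes called, and 0 held fewer. The windows lay on chromosomes 8 (6 windows), 12 (3), 1 (2), 4, 9 and 11. The window on chromosome 8 from LOC4344827 to LOC4344909 had 24 of 43 genes called (adjusted p = 1.21e-07) and included OsGER2, OsGER6 and GLP2. The window on chromosome 12 from LOC4352471 to LOC4352555 had 24 of 50 called (adjusted p = 3.27e-06) and included TRS130 and PBZ1, and LOC4352535 and LOC4352538 stood at -5.38 ± 0.09 and -4.46 ± 0.10 in NIL-BPH9.

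**Figure D4:**
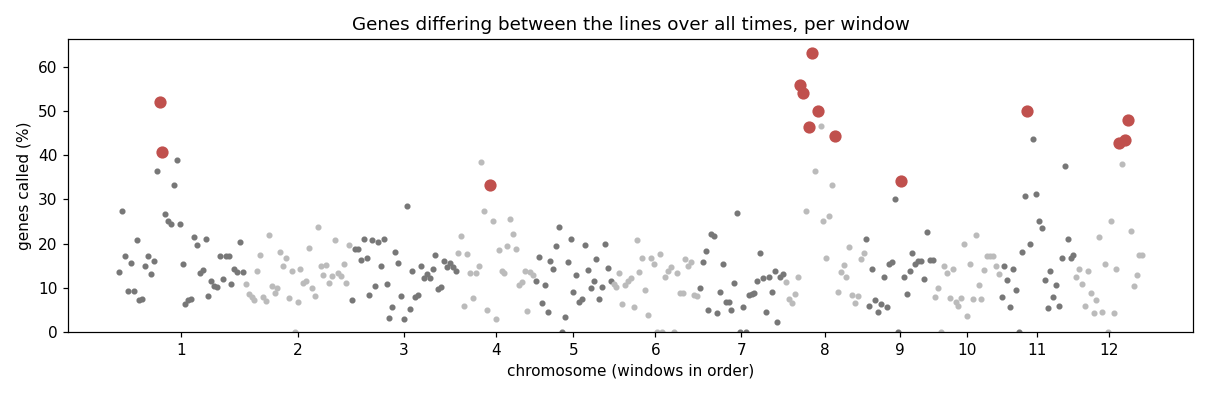
Percent of tested genes that differed between the lines over all times (y axis) in 357 windows of 1 Mb, in order along the 12 chromosomes (x axis), where large points mark the 14 windows past the threshold. The highest, on chromosome 8, had 63.2% of 19 genes called.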

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

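The tests of young tissue, of single control pairs as covariates, of signs at 0 h in the windows, of disagreement relative to size, and all tests of the JAZ pattern were chosen after the result was seen, and the bound for time of day at 0 h was widened after its values were seen. The responses of the lines were set against each other by a test of the difference itself, and 3482 probe sets at 3 h and 2325 at 6 h passed it. Of 100 permutations of line labels within times (real one included), 1 reached as many at 3 h and 1 at 6 h, and the highest other counts were 1372 and 1833. Such permutations also break a line difference that is the same at both times. They therefore ask whether the lines differ at all, and cannot decide whether the responses differ. For the lines over all times 1 of 100 reached the real 3561, and the highest other count was 1. The 10 splits of the 6 arrays of a response or of 1 time are too few for a share under 0.05: the real counts were 4906, 2521, 4660 and 6188 for the responses and 4769, 2468 and 3736 for the lines at 0, 3 and 6 h, and the highest of the others 1, 4, 1, 1, 40, 1 and 2. For gene lists called, 3 of 100 permutations of all labels reached the real 64, a share under 0.05, while the highest other gave 72 and the median of the others was 27.

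At 3 h the cell division list, whose response differed, had a median of 0.88 (adjusted p = 0.000118 with an estimated correlation). The other lists called at the preset correlation lost their calls: the medians were 1.14 for diterpene phytoalexin (adjusted p = 0.108 with an estimated correlation), 0.43 for jasmonate biosynthesis (0.0829), 0.35 for JAZ (0.0521), 0.30 for ribosomal proteins (0.396), 0.25 for primary wall (0.282), -0.13 for auxin (0.122) and -0.19 for sugar (0.0894). At 6 h the medians were 0.55 for cell division (0.000278) and 0.27 for JAZ (0.0439), and, with calls lost, 0.80 for phytoalexin (adjusted p = 0.108 with an estimated correlation) and 0.26 for ribosomal proteins (0.357). Single genes whose response was higher in NIL-BPH9 at 3 h were KSL4 (5.05), OsLIS (3.16), EXPA29 (2.76), OsPIP2;5 (2.37), GH3.8 (2.15), TIFY11C (1.96), OsCAD6 (1.96) and CYP71Z7 (1.82). Others were TIFY11A (1.53), OsMCM4 (1.44), H2B.10 (1.42), OPR1 (1.1997) and RPS10-1 (0.58). A higher response is not always a rise: EXPA29 and OsMCM4 fell in 9311 after 3 h and were already lower in NIL-BPH9 at 0 h. There OsMCM4 stood at 8.48 to 9.11 in NIL-BPH9 and at 9.82 to 10.05 in 9311. Lower responses at 3 h were those of OsBURP16 (-1.72), GRXC10 (-1.51), OsYSL13 (-1.46), IAA9 (-1.24), OsMFT1 (-1.24) and OsCIN4 (-1.03). At 6 h the higher ones were OsLIS (2.78), OsGRF5 (1.61), EXPB2 (1.52), OsYAB3 (1.51), OsCAD6 (1.46), TIFY11A (1.45), TIFY11C (1.35), CYP71Z7 (1.26), H2B.10 (1.12), OsMCM4 (0.95) and RPS27AA (0.60), and the lower ones RAB21 (-2.25), OsNAS1 (-1.76), OsHd1 (-1.40), OsGER2 (-1.06), OsSPS4F (-1.06) and SWEET11 (-0.93).

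Cell division genes were higher in 9311 at 0 h than in 9311 at 3 h and in NIL-BPH9 at 0 h, so their differing response may come from the 9311 0 h samples. A single array of that group is argued against: at least 17 of the 20 genes were called lower at 3 h whichever of its 3 arrays was left out. For RNA degradation, the median change was -0.92 with the 3' to 5' ratio as a covariate and -0.88 without it. With each of the 5 pairs alone as covariate, since the pairs moved apart, the median change was -0.91 to -0.84. That fit also held the group means, so the slope on the ratio was estimated only from the scatter of arrays within groups. The ratio in 9311 was 1.76 at 3 h and 1.61 at 0 h, and the adjustment for this shift is only as good as that slope. RNA degradation therefore stays open. More young, growing tissue in the 9311 samples at 0 h stays open: 8 of 21 measured growth-regulating factor, YABBY and KNOX genes were lower in NIL-BPH9 at 0 h and 2 were higher, between the bounds set for and against it (5 lower of the 17 not seen before), and 11 of the 21 fell in 9311 after 3 h. Time of sampling at 0 h also stays open. An effect of infestation on growth is argued against for the difference at 0 h, which preceded infestation. There at least 15 of the 20 genes were called lower in NIL-BPH9 whichever of the 3 arrays of 9311 was left out. For the fall in 9311 after 3 h such an effect stays open, without uninfested plants at 3 h or 6 h.

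Genes that differed between the lines gathered in windows. A difference that arises only after infestation is argued against: of 234 genes picked on the 3 h and 6 h arrays in 16 such windows, 190 (81.2%) had the same sign on the separate 0 h arrays, against 61.0% of those outside. Probe mismatches of a segment from another parent cannot be told apart from differences in expression. Probe sets of 1 gene disagreed 2.78 times as much inside the windows as outside (27 and 331 genes, permutation p = 0.00016), but relative to the size of each gene's own difference the ratio was 0.938 (permutation p = 0.818), so larger differences there could give the same result. Inherited differences between the lines stay open as a hypothesis.

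Of the 12 JAZ genes 6 had a higher response in NIL-BPH9 at 3 h and 1, TIFY10B, a lower one (list adjusted p = 0.0521 with an estimated correlation), and 4 a higher one at 6 h (0.0439). Jasmonate signalling already raised in 9311 at 0 h is argued against, since 0 of the 12 were called lower in NIL-BPH9 there. Between the lines at 3 h or 6 h, 0 of 7 clock genes were called (1 at an unadjusted p under 0.05). Different times of day of sampling at 3 h are argued against by OsPRR95, whose difference there with 2 SE added was 0.223. Its change over 3 h in NIL-BPH9 was -1.06 ± 0.08. At 6 h OsPRR95 and OsCCA1 differed by -0.04 ± 0.08 and -0.30 ± 0.20, where their changes in NIL-BPH9 were -0.54 ± 0.08 and -0.64 ± 0.20. A missing call with 3 arrays per group cannot decide this, so different times of day at 6 h stay open. As to different times of day of sampling in the lines at 0 h, 3 of the 7 clock genes were called there (the bound first set was at most 1). The widened bound was met, with 6 JAZ genes called higher in NIL-BPH9 and 0 lower at 0 h. A higher start works against a larger rise only in the genes that had it. TIFY11A, whose response was larger, stood at 6.53 to 7.35 in NIL-BPH9 and at 6.73 to 7.20 in 9311 at 0 h. Different times of day at 0 h therefore stay open. The number of insects per plant was not analysed here, and the lines also differed in windows on several chromosomes. Insect load, the resistance gene itself and other differences between the lines may therefore each underlie the larger response.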

How the results depend on the processing

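The 3 h and 6 h arrays alone, and leaving out arrays for chromosomes and windows, were alternatives chosen after seeing the data; the others were planned. The 10 counts of called probe sets moved by less than 1.5 times under quantile normalization, median centring, no filter, the stricter filter, the floor and the replicate block. With a 2-fold minimum they were 527, 248, 637, 923, 570, 559, 555, 603, 334 and 473 (9311 at 3 h and 6 h, NIL-BPH9 at 3 h and 6 h, lines at 0, 3 and 6 h, differences at 3 h and 6 h, lines over all times), and at an adjusted p under 0.01 they were 2947, 1346, 2563, 2921, 2729, 1409, 2035, 1781, 786 and 1927, as stricter thresholds give. With only the comparison's groups in the fit, 9311 gave 2486 and 805, the lines at 0 h 1734 and the difference at 6 h 1221, while NIL-BPH9 gave 5163 and 6293, the lines at 3 h and 6 h 3434 and 4297 and the difference at 3 h 2648. Without the trend the difference at 6 h gave 1309. The cause was not tested in either case. Median centring moved the median log2 change of NIL-BPH9 at 6 h by 0.108, and its share of rises from 44.3% to 65.3%.

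Leaving out each array gave 3656 to 5118, 1749 to 3416, 3278 to 3828, 3533 to 5268, 3727 to 5561, 1724 to 1949, 2546 to 3133, 2655 to 4552, 1424 to 4052 and 2964 to 4493 in the same order, 60 to 74 called lists, and correlations of the responses from 0.174 to 0.303 at 3 h and from 0.191 to 0.388 at 6 h. Camera with an estimated correlation called 28 of the 64 list tests. Chromosomes past the threshold went from 5 to 8 with quantile normalization and to 2 with the 3 h and 6 h arrays only (the cause was not tested), and ranged from 3 to 7 without 1 array. Windows ranged from 11 to 20 over the other settings and from 10 to 16 without 1 array. Of 230 gene results named, 24 lost their call under at least 1 alternative and 0 reversed, over 2660 alternative values. No filter and the replicate block leave a log2 change as it was, so neither could reverse it. Nor could leaving out 1 array, for genes picked because the groups compared did not overlap.

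Replicate numbers did not pair the samples: deviations of 45 pairs with the same number correlated at -0.107 to 0.0662, with 0 over 0.1, and 2 of 18 samples correlated best with their own number. With the replicate block the counts were 4591, 2310, 4253, 5787, 4400, 2264, 3440, 3167, 1979 and 3129. Signals near the array median limit what dim genes such as KSL4, Oskn1 and TIFY9 can show.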

Other observations

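The gene groups below and the split of shared arrays were chosen after the values were seen. Among genes for nicotianamine and related iron chelators, OsNAS2 was higher in NIL-BPH9 at 0 h by 1.23 ± 0.10 (limma adjusted p = 5.77e-08, n = 3 arrays per group), beside OsNAS1 at 2.52 ± 0.07 and OsNAAT1 at 1.46 ± 0.06. At 0 h OsNAS3 stood at -0.19 ± 0.08 (adjusted p = 0.129) and OsbHLH063 at 0.46 ± 0.18 (adjusted p = 0.0902), and neither passed. In 9311 OsNAS1 rose by 0.86 ± 0.07 after 3 h and by 1.45 ± 0.07 after 6 h, and in NIL-BPH9 it fell by 0.31 ± 0.07 after 6 h. OsbHLH063, a regulator of iron deficiency responses, rose in 9311 after 6 h by 0.97 ± 0.18, and OsNAS3 fell in NIL-BPH9 after 6 h by 0.48 ± 0.08. The iron transporter gene OsIRT1 did not pass the test in the 4 responses or in the 3 differences between the lines (-0.08 ± 0.18 between the lines at 0 h).

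Of 10 measured growth-regulating factor genes, 8 fell in 9311 after 3 h, and OsGRF11 and OsGRF12 did not pass (adjusted p = 0.765 and 0.473). Among the 8, OsGRF6 and OsGRF7 fell by 1.59 ± 0.09 and fell by 1.40 ± 0.10, and OsGRF1 fell by 1.51 ± 0.14. In NIL-BPH9 OsGRF3 fell by 0.46 ± 0.10 and the other 9 did not pass, with OsGRF6, OsGRF7 and OsGRF1 at -0.21 ± 0.09, -0.17 ± 0.10 and -0.33 ± 0.14. At 0 h 7 of the 10 were already lower in NIL-BPH9 than in 9311 and 0 were higher. OsGRF6, OsGRF7 and OsGRF1 stood there at -1.16 ± 0.09, -1.05 ± 0.10 and -1.26 ± 0.14, and the 9311 0 h arrays enter both comparisons. The difference of the responses passed for 6 of the 10, among them those 3 with limma adjusted p of 9.22e-07, 9.21e-06 and 0.000484. It did not pass for OsGRF3 (0.200), OsGRF8 (0.767), OsGRF11 (0.735) and OsGRF12 (0.675).

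The changes at 3 h in 9311 and the differences between the lines at 0 h shared the 9311 0 h arrays. They correlated across genes at 0.490, where the simulated value without any effect was 0.503, and their covariance was 0.0856 against a simulated 0.0317, an excess of 0.0540. Genes lower in both numbered 995. Independent lists would give 184, but lists that share arrays are not independent, so 184 is not the value without any effect. With the 3 arrays split 1 and 2 between the comparisons, so that none was shared, the 6 splits gave a covariance of 0.0363 to 0.0616 and an r of 0.150 to 0.312.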
